A study of Homo sapiens with 22 samples.

How the data were processed

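RNA of human embryonic kidney (HEK-293) cells was measured on 22 Affymetrix human oligonucleotide arrays of a single design in which each gene is read by 1 or more probe sets. The labels name 5 monoclonal lines with high store-operated calcium entry (SOCE; 12 arrays), 3 with low SOCE (6 arrays) and the parental population (4 arrays). They give each array an experiment number, with 14 arrays in experiment 1 and 8 in experiment 2, and each line in an experiment has 2 arrays, called here a unit, which makes 11 units. The line H36 and the parental cells were run in both experiments. The labels do not say whether the arrays of a pair come from separate cultures, so p-values computed between single arrays measure only the spread within such pairs, which may be technical only.

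The deposited values are probe set intensity values on a linear scale, from 0.1 to 44811.6, for 22215 probe sets. The program that summarised them is not given in the sources used here. After trimming 2 percent from each end, the array means ran from 497 to 499, so the arrays had been scaled to a common mean, and the values were used as deposited with no further normalization. Array medians ran from 146.9 to 263.5. No count of molecules underlies an array value, and the number of arrays limits the precision.

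Values were taken as log2(intensity + 39.7), the offset being the 20th percentile of all values, so fold changes of dim genes are understated. The probe annotation gave 1 symbol for 19065 probe sets and several for 1043, and it did not list 2107, which stayed unnamed. Symbols were checked through gene identifiers against the RefSeq annotation of GRCh38.p14, which was otherwise used only for which genes neighbour each other. Each gene was represented by its probe set with the highest mean, giving 11963 genes. A probe set was kept if it lay above the 40th percentile of its unit's values in at least 3 units, which left 9094 genes for the tests.

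Group comparisons used limma 3.58.1 in R 4.3.3 on the log2 means of the 11 units, with group and experiment as terms and the clone as a random block. The block correlation was -0.283 and 7 residual degrees of freedom remained. This correlation is poorly determined, since only H36 and the parental cells were run in both experiments, and the number of genes past the threshold depends on it. A negative value treats runs of the same line as less alike than runs of different lines, the reverse of what such a block is for. For high against low lines, 14 genes passed with it and 9 with no clone block. Moderated p-values were adjusted over genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the threshold. Fold changes between groups are those of this fit, adjusted for experiment, and so differ from differences of the group means. The experiment term assumes the same shift in every line. Yet the shift differed between H36 and the parental cells for 3749 genes, with the spread within array pairs as the error. The groups were unevenly spread over the experiments, so their differences and p-values rest on this assumption. Single clones were compared with the parental arrays of their experiment by limma on the 22 arrays, and there a call also needed a 2-fold difference. The moderated F test of limma gave the differences among the clones of experiment 1. The experiments were compared through the 8 arrays of H36 and the parental cells. The 26 gene lists were tested by camera in limma with a preset correlation of 0.01 and again with an estimated one.

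The tests, the gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. For high against low clones, the rule names genes past the threshold with the same sign in both experiments, up to 12 per direction by fold change, filled to 6 by smallest p. It names 6 per direction against the parental cells, 3 per direction for each clone, 12 with the largest range among clones, and 4 per direction between experiments. For each list it names members past the threshold over the list alone, or else the 2 with the smallest p, and it always names a fixed set of SOCE genes, of which 1 is not reported here. A few further genes are marked where they were chosen after their values were seen.

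The fits were tested on simulated data made from the measured gene means and spreads. The simulated noise was independent, with the same spread for a gene in every unit or array and no clone effect. Weights estimated for the measured units ran from 0.33 to 2.97, so the simulated recovery may not hold for the measured data. For high against low clones, over 9094 genes, 56% of genes changed 2-fold were recovered, 98% of those changed 4-fold and 100% of those changed 8-fold. In that simulation 17 unchanged genes were called, and 0 were called when no gene changed. For a single clone against the parental cells, 90% of genes changed 4-fold were recovered over 9094 genes. Alternative settings covered the offset, quantile normalization, the filter, the probe set rule, the experiment term, the clone block, the treatment of array pairs, the variance prior, each experiment alone and each clone left out. Settings chosen after seeing the data left out units that stood apart or used array weights.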

Results

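Gene expression was measured in monoclonal HEK-293 lines with high or low store-operated calcium entry, the influx of calcium through the plasma membrane that follows emptying of the endoplasmic reticulum store. The high SOCE lines were H1, H15, H24, H36 and H39, and the low SOCE lines were L3, L28 and L29. Experiment 1 held all 5 high lines, L3 and the parental cells, and experiment 2 held H36, L28, L29 and the parental cells. Arrays of a pair correlated with r between 0.95 and 0.989 across genes. The arrays of high lines in experiment 1 had the highest median intensities on average, with ranges that overlapped: the lowest was 189.3 in H15 and the highest of the other arrays 192.2 in L3. Their mean was 217.3 ± 24.5 (SD, n = 10 arrays), against 171 ± 15.8 (SD, n = 4) for L3 and the parental cells of that experiment and 158.3 ± 9.69 (SD, n = 8) for experiment 2.

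**Figure D1:**
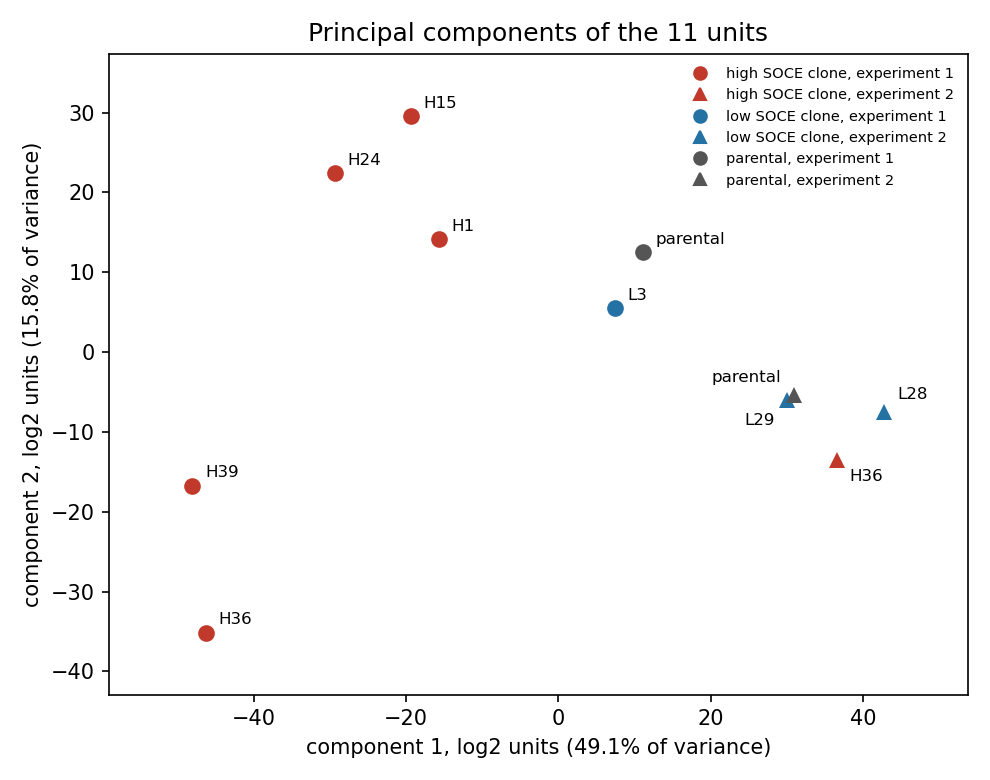
Principal components of log2 gene levels for the 11 units, each point the mean of 2 arrays; colour gives the group and shape the experiment. The first component, 49.1% of the variance, places the high lines of experiment 1 between -48.09 and -15.67 and all other units between 7.452 and 42.83.

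The comparison of high with low SOCE lines addressed which genes differ with the level of calcium entry. Of 9094 genes, 10 were higher and 4 lower in the high lines. The largest rise was in SPARC, a secreted matrix glycoprotein, with a log2 difference of 2.65 (SE 0.35; adjusted p = 0.015, limma). Its level was 9.24 ± 0.48 (SD, n = 5 clones) in high lines and 7.29 ± 1.31 (SD, n = 3) in low lines, with 9.46 in the parental cells. Both chains of the class II molecule HLA-DP were higher, HLA-DPB1 by 2.52 (SE 0.32; adjusted p = 0.013, limma) and HLA-DPA1 by 2.42 (SE 0.40; adjusted p = 0.037, limma). CYBA, a membrane subunit of the NADPH oxidase, was higher by 2.51 (SE 0.38; adjusted p = 0.022, limma).

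Of the other genes higher in high lines, SIX2, a transcription factor of kidney progenitors, was higher by 1.91 (SE 0.27), the pseudokinase gene TRIB2 by 2.26 (SE 0.38) and SMAD6, an inhibitor of BMP signalling, by 1.24 (SE 0.21). The retroviral envelope gene ERVMER34-1 was higher by 1.72 (SE 0.25), the synaptic vesicle gene SV2A by 1.64 (SE 0.24) and THAP3 by 1.36 (SE 0.20). Among the genes lower in high lines, the zinc finger gene ZNF532 differed by -3.05 (SE 0.51; adjusted p = 0.040, limma) and the cancer-testis antigen gene MAGEA1 by -2.53 (SE 0.30; adjusted p = 0.013, limma), read by a probe set that may also match related genes. The teneurin gene TENM1 differed by -1.86 (SE 0.32) and the lysine methyltransferase gene SMYD3 by -1.31 (SE 0.19). TFB2M at -1.22 (SE 0.24) and CDH12 at -1.70 (SE 0.34) did not pass (adjusted p = 0.10 each, limma). Second probe sets past the filter gave the same sign with smaller differences, 1.46 (SE 0.28) for SPARC, 1.02 (SE 0.18) for SIX2, 1.01 (SE 0.30) for TRIB2 and 1.62 (SE 0.34) for HLA-DPA1, while a dim second probe set of THAP3 gave 0.05 (SE 0.17) and the others of SMAD6 gave 0.33 to 0.49.

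**Figure D2:**
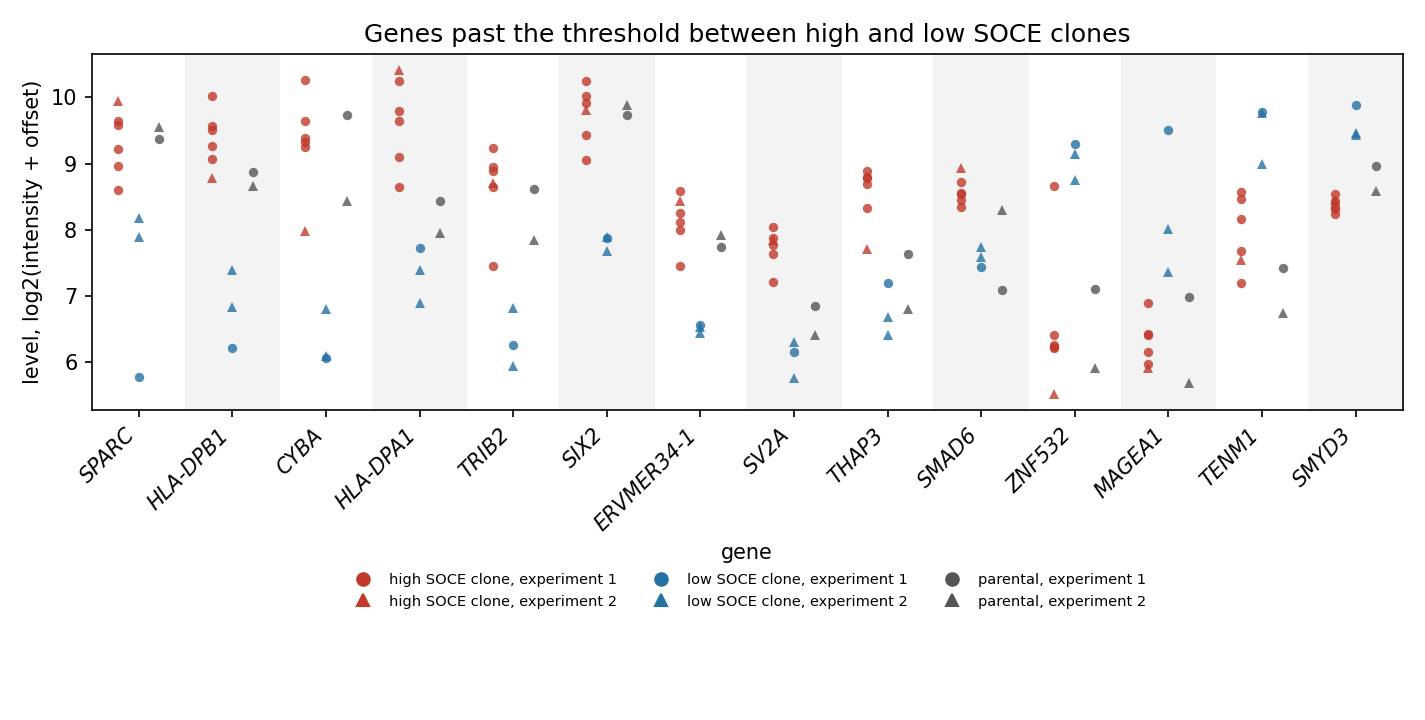
Levels, as log2(intensity + offset), of the 14 genes past the threshold; each point is a unit (mean of 2 arrays), coloured by group, with circles for experiment 1 and triangles for experiment 2. SIX2 lies between 7.68 and 7.90 in the low lines and between 9.05 and 10.25 in the high lines.

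All 14 genes differed in the same direction within each experiment. A fit to both experiments chose these genes, so a shared sign was favoured beforehand and is not a replication. Over all tested genes, the high minus low differences of experiments 1 and 2 correlated at r = 0.183. SPARC differed by 3.42 in experiment 1 and 1.90 in experiment 2, and ZNF532 by -2.54 and -3.44. After quantile normalization 0 genes passed (smallest adjusted p = 0.065, limma; 840 genes with an unadjusted p under 0.05), although the 14 genes kept their sign with 0.86 to 1.04 of their log2 difference. The count also fell to 9 with no clone block, whose correlation of -0.283 is poorly determined. It was 0 without L28, 1 without L3, 5 without L29 and 8 without H24, and rose to 47 without H36 and 106 without H1. Array weights gave 1397 with the clone block and 1306 without it. The genes called changed as well as their number. Of the 14 genes, 0 were among the calls without L3, 4 without L29, 7 without H36 and 14 without H1.

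None of the 7 measured genes of the SOCE list passed the threshold, and 0 had an unadjusted p under 0.05 (limma). STIM1, the calcium sensor of the endoplasmic reticulum, differed by 0.23 between high and low lines (SE 0.21; adjusted p = 0.62, limma), with 0.35 in experiment 1 and -0.01 in experiment 2. The channel genes ORAI2 and ORAI3 differed by 0.21 (SE 0.18; adjusted p = 0.59, limma) and 0.38 (SE 0.27; adjusted p = 0.54, limma), the latter with -0.18 in experiment 2. Over the settings tried, STIM1 ranged from -0.01 to 0.63 (smallest adjusted p = 0.18, limma) and ORAI3 from -0.18 to 0.85 (smallest adjusted p = 0.076), with 0.63 and 0.71 without the experiment term and 0.45 and 0.85 without H36. TRPC1 differed by 0.21 (SE 0.24; adjusted p = 0.70, limma). STIMATE at 0.45 (SE 0.21) and SARAF at -0.35 (SE 0.18) had the smallest p of the 7 tested members of the SOCE list, and 0 members passed over all genes or adjusted over the list alone. STIM2 and ORAI1 had no probe set with a single symbol and were not analysed here, and TRPC4, TRPC5, TRPC6 and TRPC7 were too dim to be tested.

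None of the lists of calcium genes passed the threshold as a group. The mean log2 difference was 0.11 for the SOCE list (adjusted p = 0.566, camera), 0.26 for TRP channels (adjusted p = 0.358), -0.09 for the 25 tested genes of the endoplasmic reticulum store (adjusted p = 0.359) and 0.07 for plasma membrane export (adjusted p = 0.988), whose test statistic pointed down. It was 0.26 for voltage-gated calcium channels (adjusted p = 0.358), 0.04 for Gq and phospholipase C signalling (adjusted p = 0.857), 0.12 for calmodulin, calcineurin and NFAT (adjusted p = 0.566) and -0.04 for protein kinase C (adjusted p = 0.566). The S100 and annexin list had a mean of 0.05 with a test pointing down (adjusted p = 0.762), mitochondrial calcium genes -0.08 (adjusted p = 0.464), caveolar and scaffold genes -0.09 (adjusted p = 0.359) and potassium channels 0.29 (adjusted p = 0.218). No member of these lists passed over all genes or adjusted over the list alone, and 0 to 4 members per list had an unadjusted p under 0.05 (limma).

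The members with the smallest p in these lists did not pass. RYR2, a calcium release channel gene, differed by -1.43 (SE 0.43) and PDIA6 by -0.67 (SE 0.21). ANXA11 differed by -1.24 (SE 0.38), S100A13 by 0.66 (SE 0.22) and CAV1, the caveolin gene, by -0.92 (SE 0.36), while STX1A differed by 0.53 (SE 0.23). The calcineurin gene PPP3CA differed by -0.63 (SE 0.25) and its regulator RCAN2 by 0.62 (SE 0.23). The muscarinic receptor gene CHRM3 differed by -0.70 (SE 0.29), RGS16 by -0.70 (SE 0.25), PRKCQ by 0.52 (SE 0.20) and PRKD3 by -0.42 (SE 0.20). The channel genes TRPM3 at 0.53 (SE 0.28), TRPM8 at 0.74 (SE 0.43), CACNA1A at 0.47 (SE 0.25), CACNG2 at 0.44 (SE 0.26), KCNA1 at 0.86 (SE 0.30) and KCNC1 at 0.70 (SE 0.32) were positive. For export and mitochondria the values were 0.38 (SE 0.33) for SLC24A2, -0.19 (SE 0.24) for ATP2B4, -0.65 (SE 0.32) for SLC8B1 and 0.57 (SE 0.29) for MICU2.

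Of the 26 lists, 3 passed with the preset correlation and 0 with an estimated correlation (adjusted p = 0.72 for each of the 3). Genes of cholesterol and sterol synthesis were lower in high lines, with a mean of -0.38 over 19 genes (adjusted p = 0.00134, camera). MSMO1, a sterol oxidase gene, differed by -0.96 (SE 0.21), and it alone passed adjusted over the list alone, with 0 passing over all genes. The list mean was -0.51 in experiment 1 and -0.12 in experiment 2, and the call ended in experiment 2 alone (adjusted p = 0.65) and without the experiment term (mean -0.24; adjusted p = 0.06). Cytosolic ribosomal protein genes had a mean of 0.40 over 30 genes (adjusted p = 3.53e-06, camera), with all 30 positive, among them RPS27 at 0.54 (SE 0.24) and RPS3 at 0.57 (SE 0.25), which did not pass singly. Their mean was 0.70 in experiment 1, where the high lines had the higher array medians on average, and -0.13 in experiment 2, and it was 0.03 after quantile normalization (adjusted p = 0.69). Fibroblast markers, fixed as a sign of other cells, had a mean of 0.40 over 10 genes (adjusted p = 0.0498, camera), with 0.60 in experiment 1 and -0.03 in experiment 2, and FBLN1 at 0.76 (SE 0.26) and THY1 at 0.71 (SE 0.26) had the smallest p without passing. The fibroblast call ended in most settings, among them quantile normalization (mean 0.29; adjusted p = 0.17), either other offset, either other filter, no clone block, the 22 arrays, the first or the duplicate arrays, the intensity trend, no parental units, array weights with no clone block, and without H36, H39 or L28, while the mean was 0.67 without the experiment term (adjusted p = 0.014). Without L3 all 3 calls ended, with means of -0.26, 0.16 and 0.26, and without H36 and H39 of experiment 1 the sterol call ended at -0.22.

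Extracellular matrix and adhesion genes held the most members past the threshold when adjusted over the list alone, 7 of 36, against 1 over all genes, SPARC. FN1, the fibronectin gene, differed by 1.07 (SE 0.25), CD44 by 1.57 (SE 0.44) and the basement membrane collagen gene COL4A1 by 1.12 (SE 0.31). The other members, named after their values were seen, were COL4A5 at 1.02 (SE 0.30), FBN1 at 1.09 (SE 0.34) and COL4A2 at 0.98 (SE 0.32). FN1 differed by 1.09 and 1.01 in experiments 1 and 2, and COL4A1 by 0.68 and 1.58. As a group the list did not pass (mean 0.25, adjusted p = 0.145, camera). Of its 36 members 21 were higher in high lines, and 15 were higher within experiment 2. Among the lower members, NID1 at -0.75 (SE 0.28) and COL5A2 at -0.66 (SE 0.25) had the smallest p without passing. Kidney and epithelial genes had a mean of 0.30 (adjusted p = 0.0853), with SIX2 past the threshold over all genes and over the list alone.

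The other lists did not pass as groups. Mean log2 differences were -0.14 for the unfolded protein response (adjusted p = 0.358, camera), 0.19 for immediate early genes (adjusted p = 0.359), 0.02 for the cell cycle with a median of -0.06 and a test pointing down (adjusted p = 0.748), -0.05 for cadherins and junctions (adjusted p = 0.513) and 0.22 for neuronal genes (adjusted p = 0.358). Glycolysis and hypoxia genes had a mean of -0.07 (adjusted p = 0.464) and interferon response genes 0.12 (adjusted p = 0.358). Their single members past the threshold adjusted over the list alone were the glucose transporter gene SLC2A3 at 1.33 (SE 0.26) and the antiviral gene OAS3 at 1.38 (SE 0.26), and 0 passed over all genes. Leukocyte markers had a mean of 0.27 (adjusted p = 0.358), although LCP1, which passed adjusted over the list alone, differed by -0.86 (SE 0.26). Markers of keratinocytes or carcinoma lines had a mean of 0.26 (adjusted p = 0.415). The members with the smallest p that did not pass were TRIB3 at -0.85 (SE 0.30) and CHAC1 at -1.32 (SE 0.52) for the unfolded protein response, MYC at -1.45 (SE 0.41) and NR4A1 at 0.68 (SE 0.33) for immediate early genes, and CDC20 at 0.72 (SE 0.27) and CDK1 at 0.64 (SE 0.27) for the cell cycle. PCDH17 differed by -0.66 (SE 0.26), CTNNA1 by -0.45 (SE 0.19), the neurofilament genes INA by 1.13 (SE 0.43) and NEFL by -0.61 (SE 0.24), ELF3 by 0.56 (SE 0.29) and S100A2 by 0.29 (SE 0.29).

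Against the parental cells, no gene passed the threshold in the high lines as a group (smallest adjusted p = 0.182, limma). An unadjusted p under 0.05 was found for 1451 genes (limma). The parental control is a single population run in both experiments, so it has no independent replicates. The comparison of the low lines with the parental cells uses the same control. The smallest p among positive differences belonged to THAP3 at 1.05 (SE 0.19), ZFX at 1.16 (SE 0.22), UBQLN4 at 1.38 (SE 0.27), SMAD6 at 1.05 (SE 0.20), RUFY2 at 1.54 (SE 0.30) and LIF, a cytokine gene, at 1.47 (SE 0.30). Among negative differences they were PPP2R2D at -1.46 (SE 0.25), AMBN at -2.16 (SE 0.40), the kinase gene PRKCD at -1.32 (SE 0.25), MAD1L1 at -1.65 (SE 0.32), RNASET2 at -1.20 (SE 0.23) and TRABD at -1.76 (SE 0.36). Without H36 the count was 74, without H15 it was 6 and without H1 it was 2, and array weights gave 683 with the clone block and 114 without it.

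The low lines as a group also had no gene past the threshold against the parental cells (limma; smallest adjusted p = 0.0528; 439 genes with an unadjusted p under 0.05). TENM1 was at 2.51 (SE 0.35), MAGEA1 at 2.15 (SE 0.33), ZNF532 at 2.72 (SE 0.56), KLHL2 at 1.24 (SE 0.23), FUT4 at 1.10 (SE 0.22) and RAB3GAP1 at 1.16 (SE 0.25). On the negative side SIX2 was at -1.98 (SE 0.30), the homeobox gene MSX2 at -1.43 (SE 0.21), CYBA at -2.61 (SE 0.42), SPARC at -2.37 (SE 0.38), HLA-DPB1 at -1.95 (SE 0.35) and the growth factor gene BMP2 at -3.66 (SE 0.70). Leaving out 1 clone gave 15 genes without H1, 9 without H15, 3 without H24 and 1 each without H39 and L3, experiment 2 alone gave 10, and array weights gave 160 with the clone block and 53 without it.

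Each clone was also set against the parental cells of its own experiment, with the spread between arrays of a pair as the error. In H36 and H39 of experiment 1 the stress-induced cytokine gene GDF15 was higher by 5.37 and 5.48 (SE 0.19 each), HMOX1, the heme oxygenase gene, by 4.87 and 4.79 (SE 0.18 each) and S100P by 3.90 and 4.67 (SE 0.23 each). In L28 and L29 the reductase gene DHRS2 was higher by 4.94 and 5.31 (SE 0.21 each) and MAGEA6 by 4.65 and 4.19 (SE 0.47 each), while BMP2 was lower, at -3.95 and -3.98 (SE 0.24 each), as was the insulin receptor substrate gene IRS2, at -2.92 and -2.85 (SE 0.24 each). L28 also had ZNF532 at 3.23 and ZNF22 at -2.77, and L29 had TENM1 at 3.01 and CALCB at -2.51. H1 also had higher HMOX1 at 4.13 and DHRS2 at 4.11 with IL32 at 3.62, and lower BMP2 at -3.11, ZNF711 at -3.50 and the kidney transcription factor gene WT1 at -2.47.

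In L3 the genes MAGEA1 at 2.53, GDF15 at 2.47 and PTPRO at 2.43 were higher, and CYBA at -3.66, SPARC at -3.59 and the adhesion gene ICAM2 at -3.14 were lower. H15 and H24 shared higher NOTCH2NLA, at 3.12 and 4.07, and MZT2B, at 3.13 and 3.41, and lower ZNF711, at -3.93 and -3.79. These changes were not particular to H15 and H24. In H1, H36 and H39 of experiment 1, log2 levels of MZT2B were 9.53, 10.41 and 9.23, against 6.77 in the parental cells. Those of NOTCH2NLA were 9.24, 9.95 and 9.88, against 7.57. H15 also had ATP8B1 at 2.70, the chaperone gene HSP90B1 at -3.28 and GALK1 at -3.20, and H24 had SLC35D2 at 3.28, SERPINF1 at -4.24 and the serine synthesis gene PSAT1 at -3.93. TMEM47 was lower in H36 in both experiments, at -3.81 and -3.90, and in H39 at -4.64. It was also low in H24, at a log2 level of 7.54 against 11.22 in the parental cells of experiment 1. H36 of experiment 2 further had ARC at 2.47, HLA-DPA1 at 2.46, EFNB2 at 2.07, LGALS3BP at -2.86 and PSMD5 at -2.81, and H36 of experiment 1 had TST at -3.50 and TBCD at -3.21. H39 also had ZNF711 at -4.17 and PAGR1 at -3.42.

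The number of genes past the threshold and at least 2-fold from the parental cells was 505 in H1, 731 in H15, 1155 in H24, 2023 in H36 and 1691 in H39 of experiment 1, against 134 in L3 of the same experiment (limma). In experiment 2 it was 76 in H36, 148 in L28 and 132 in L29. After quantile normalization the counts were 1778 in H36 and 1547 in H39 of experiment 1, 115 in L3 and 56 in H36 of experiment 2.

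**Figure D3:**
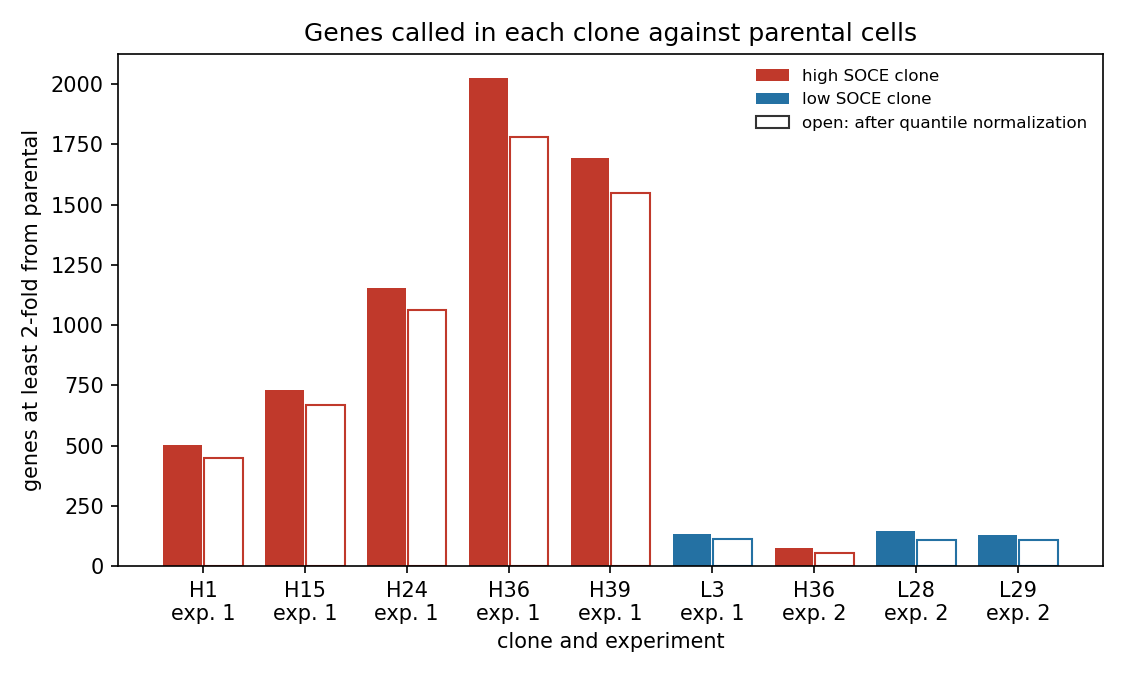
Number of genes past the threshold and at least 2-fold from the parental cells of the same experiment, for each clone and experiment; filled bars show values as deposited and open bars show quantile-normalized values. H36 has 2023 genes in experiment 1 and 76 in experiment 2.

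Differences among the 6 clones of experiment 1 covered 3946 of the 9094 genes, 43.4% (moderated F test, limma, and at least 2-fold between the highest and lowest clone). The error was the spread between arrays of a pair, so the count cannot separate differences between clones from those between cultures or arrays. Between the experiments, H36 had 2744 genes past the threshold and at least 2-fold from itself, and the parental cells had 429. The widest ranges, as log2 between extreme clones, were 5.88 for GDF15, highest in H39 and lowest in H15, 5.06 for DHRS2, highest in H1, and 4.76 for TMEM47, lowest in H39. GADD45B had a range of 4.31, HMOX1 4.30 and the chemokine gene CXCL8 4.08. S100P spanned 4.65, SERPINF1 4.35, IRS2 4.21, NOTCH2NLA 4.20, CYBA 4.19 and ICAM2 4.10. CYBA was lowest in L3, at 6.07, and ranged from 9.25 to 10.26 in the high clones of that experiment.

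The experiments were compared through H36 and the parental cells, the only cells run in both. In experiment 2, 962 genes were higher and 1757 lower (limma). Higher genes included RAC3, a small GTPase gene, at 2.61 (SE 0.22), the kinase gene MARK2 at 2.45 (SE 0.17), HELLS at 2.37 (SE 0.14) and MPHOSPH8 at 2.34 (SE 0.56), the last with 3.86 in H36 and 0.81 in the parental cells. Lower genes included the receptor kinase gene TEK at -2.38 (SE 0.24), DPM3 at -2.30 (SE 0.21), LUZP4 at -2.05 (SE 0.26) and CHI3L1 at -2.03 (SE 0.26). H36 alone had 2014 higher and 3177 lower genes, and the parental cells alone had 699 and 1051. The difference itself passed for 3749 genes (interaction term, limma), and across genes H36 of experiment 1 correlated with H36 of experiment 2 at r = 0.826, against 0.95 for the parental cells.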

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

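The tests of an exchanged sample and of stress genes, that of quantile normalization on the 14 genes, and the count of splits with L28 and L29 both in the group of 3 were chosen only after the results they bear on had been seen. Among the 16 named genes of the high and low comparison, tested for a clone far from the other high clones, ZNF532 in H1 stood out, at 8.66 against 5.87 to 6.41 in H15, H24, H36 and H39. Chance alone gives about 1 such gene in 20. The high minus low difference itself differed between experiments for 1 gene, the cancer-testis antigen gene MAGEA6 (adjusted p = 0.033, limma interaction; 500 genes with an unadjusted p under 0.05). It was 0.15 in experiment 1 and -5.41 in experiment 2, with 12.15 in L28 and 11.69 in L29 against 6.81 in L3. L3 was the only low line of experiment 1 and H36 the only high line of experiment 2, so the other units give the spread, and a difference between clones cannot be separated here from a difference between experiments.

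The change from experiment 1 to experiment 2 differed between H36 and the parental cells for 3749 genes. HMOX1 was at 13.67 in H36 of experiment 1 and 9.35 in experiment 2, against 8.80 and 9.73 in the parental cells. The spread of array intensities does not account for this, since after quantile normalization H36 still had 5.02 times as many genes at least 2-fold apart between experiments as the parental cells, against 5.59 times as deposited. An exchanged sample stays open. Over the 76 genes called in H36 of experiment 2, H36 of experiment 1 correlated at r = 0.54 across genes, H24 at 0.55 and H39 at 0.51. The difference from the best other clone was -0.01 (95% interval -0.16 to 0.13). H36 lay above H1 by 0.38 (0.15 to 0.61), above H15 by 0.51 (0.30 to 0.72) and above L3 by 0.23 (-0.06 to 0.50). ZNF711 was at 10.11 and 11.31 in H36 of experiments 1 and 2 against 6.84 to 7.51 in the other high lines. It was also at 9.95 in L3 and at 11.01 and 11.34 in the parental cells, so its level does not mark H36 alone. It does set both H36 units apart from H24 and H39, at 7.23 and 6.84, but a single gene cannot decide. Across all tested genes, H36 of experiment 1 correlated at r = 0.946 with H39, run in the same experiment, and at 0.826 with H36 of experiment 2. Cell stress in experiment 1 stays open: the unfolded protein response list had a median excess of 0.24 in H36 of that experiment (percentile 98.1 of 10000 random lists matched on level), but it did not stand out among the 26 lists, with ribosomal proteins at 1.17 (percentile 100), immediate early genes at 0.80 (99.6), interferon response genes at 0.85 (99.3) and sterol synthesis at -0.68 (0.6), and with markers of keratinocytes or carcinoma lines at 1.38 (96.8) and of fibroblasts at 1.10 (95.7).

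Of the 56 ways to split the 8 clones into 5 and 3, 2 gave at least the real 14 genes, with the block correlation held at its value for the real groups. As a test of chance this share needs interchangeable lines. They were not, since most lines were run in a single experiment, and H36, run in both, gives its side of a split an extra unit. The share therefore does not exclude chance at the 0.05 level. Among the 6 splits that put L28 and L29, the lines run in experiment 2 alone, both in the group of 3, as the real groups do, the real one gave 14 genes and the highest other 2, and 6 splits are too few for a share under 0.05. The other large split of the 56, H24, H36 and H39 against the rest, which has L28 and L29 together in the group of 5, gave 130 genes, which points to a structure of the samples larger than the SOCE grouping; with the block correlation re-estimated on 1000 genes it gave 177, and the real groups 9. The higher average array medians of the high lines in experiment 1 do not account for the size of the differences, whose median ratio after quantile normalization was 0.94, but the calls ended there, with the median SE of the 14 genes going from 0.31 to 0.35 and the block correlation from -0.283 to 0.012, and the share of each in ending the calls was not separated. Other differences between the lines that follow the SOCE grouping stay open.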

How the results depend on the processing

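Settings added after seeing the data were those without units that stood apart and those with array weights; all others were planned. The 14 genes between high and low lines kept their sign in every setting that tested them, but the count of calls was unstable and moved in most settings; the cause was not tested unless stated.

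For high against low lines, higher and lower genes numbered 7 and 2 with 0.25 times the offset, 4 and 4 with 4 times the offset, 0 and 0 after quantile normalization, 5 and 1 with the 60th percentile filter, 7 and 2 with no clone block, 7 and 1 on the first arrays, 3 and 0 on the duplicate arrays, and 2 and 1 without the parental units. Treating 22 arrays as separate samples gave 41 and 49, since array pairs then count as replicates. Experiment 1 alone, with 1 low line, gave 0 and 0, and experiment 2 alone, with 1 high line, gave 17 and 23; there the lone line is assumed to vary like the other groups. Without the experiment term, and with the clone block kept, 11 and 3 genes passed. Without H36 of experiment 1 the counts were 7 and 2. Array weights gave 836 and 561 with the clone block correlation kept and 771 and 535 with no clone block; the weights favoured the low lines, at 1.92 to 2.97 against 0.33 to 0.91 for high units. Leaving out each clone gave 0 to 54 higher and 0 to 52 lower genes. No clone correlation could be estimated without H36, without its unit of experiment 1, without the parental units or in a single experiment, and the units were then taken as independent.

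Against the parental cells, high lines had 1 gene in experiment 2 alone, 683 with array weights and 114 with array weights and no clone block, and 0 to 74 with each clone left out. Low lines had 4 with 4 times the offset, 5 with no filter, 4 on 22 arrays, 1 on the duplicate arrays, 5 with the intensity trend, 10 in experiment 2 alone, 1 without H36 and H39 of experiment 1, 160 with array weights and 53 with array weights and no clone block, and 0 to 15 with each clone left out.

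The lists past the threshold numbered 1 after quantile normalization, 1 without H36 and H39 of experiment 1, 0 with an estimated correlation, and 1 to 5 with each clone left out. Fibroblast markers had a mean of 0.46 with 0.25 times the offset, 0.27 with 4 times the offset, 0.29 after quantile normalization, 0.28 with no filter and with the 60th percentile filter, 0.39 with no clone block, 0.34 on 22 arrays, 0.44 on the first arrays, 0.35 on the duplicate arrays, 0.40 with the intensity trend and with an estimated correlation, 0.32 without the parental units, 0.27 without H36 and H39 of experiment 1, 0.33 without H36 of experiment 1 and 0.50 with array weights and no clone block, none past the threshold; leaving out each clone gave 0.26 to 0.57. Sterol synthesis genes had -0.24 without the experiment term, -0.12 in experiment 2 alone, -0.22 without H36 and H39 of experiment 1 and -0.38 with an estimated correlation, none past the threshold, and -0.44 to -0.26 with each clone left out. Ribosomal protein genes had 0.0295 after quantile normalization and 0.40 with an estimated correlation, neither past the threshold, and 0.16 to 0.65 with each clone left out. Without L3, none of the 3 lists passed. In experiment 2 alone the sign turned for ribosomal protein genes (-0.13), fibroblast markers (-0.0271), STIM1 (-0.00968) and ORAI3 (-0.18).

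Calls summed over the 9 clone comparisons numbered 6595, against 2964 with 4 times the offset, 15160 at 1.5-fold and 1620 at 3-fold. Among the 6 clones of experiment 1 these settings gave 2366, 6125 and 1196 genes. Between experiments, H36 alone gave 2014 higher and 3177 lower genes and the parental cells alone 1051 lower. For dim genes the offset limits the fold change that can be seen.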

Other observations

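All tests in this part were chosen after the values were seen. The low lines L28 and L29 shared 78 genes past the threshold and at least 2-fold from the parental cells in the same direction, and 0 in opposite directions. Independent lists would share 1.1. Simulated unchanged lines set against the same parental arrays shared 0, but unchanged lines give almost no calls, so this 0 decides nothing. The high line H36 of experiment 2, set against the same parental arrays, shared 17 calls in the same direction with L28. Independent lists would share 0.6 there. Part of the excess between L28 and L29 may come from the shared controls. Their correlation across genes was 0.70 against 0.50 simulated, and the covariance 0.121 against 0.034 simulated. The simulated r holds noise and shared controls alone, so it is no baseline for lines that differ from the parental cells. H36 of experiment 2 and L28 had r = 0.44, below the simulated 0.50. The high line H1 and the low line L3, which share parental arrays, also had r = 0.44. They shared 59 calls in the same direction, where independent lists would share 3.7. Some of the 78 genes shared by L28 and L29 are named here, chosen after their values were seen. Higher genes included QPCT at a mean of 2.55, CLEC2B at 2.80 and IFITM3, an interferon-induced gene, at 2.21. The cancer-testis antigen gene MAGEC1 was at 2.57 and RYR2, a calcium release channel gene, at 1.68. Lower genes included the creatine transporter gene SLC6A8 at -2.17, the hormone subunit gene CGA at -2.00 and LTBR at -1.83. L3, run in experiment 1 against other parental arrays, shared 36 calls in the same direction with L28 and 37 with L29, and 1 in opposite directions with each, where independent lists would share 1.1 and 1.0. The high line H1 shared about as many, 35 with L28 and 38 with L29, where 3.9 and 3.7 would be shared by independent lists, with 6 and 1 in opposite directions.

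Over these 78 genes the difference of other clones from the parental cells was set against the mean of L28 and L29. Across genes, which are not independent replicates, r was 0.74 in L3 (95% interval 0.61 to 0.86) and 0.67 in H1 (0.43 to 0.85), a high SOCE line. It was -0.39 in H15, -0.08 in H24, -0.18 in H36 and -0.25 in H39 of experiment 1, and 0.31 in H36 of experiment 2, which shares its parental arrays with L28 and L29. Levels peculiar to the parental cells in both experiments would raise r in every clone. The lowest value, -0.39 in H15 (95% interval -0.55 to -0.19), argues against such levels as the whole cause. Levels peculiar to the parental arrays of experiment 2 would not raise r in clones of experiment 1, so H15 cannot test them. QPCT was at 1.88 in L3 and 2.00 in H1, and between -1.88 and -1.06 in the other high lines of experiment 1, while DHRS2 was at 4.11 in H1 and 0.10 in L3.

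A candidate explanation is that L3, L28 and L29 share regions of altered gene dosage, as lines of common descent would. Means of 40 neighbouring genes, computed without the 78 genes, correlated at r = 0.55 between L3 and the mean of L28 and L29, above all 1000 shuffles of the gene order, whose median was 0.27. The same test also lay near the top of its shuffles in the high lines H1, at 0.27 against a shuffled median of 0.16 (percentile 98.9), and H36 of experiment 1, at 0.11 against -0.01 (98.8). It was 0.53 against 0.45 in H36 of experiment 2 (97.3) and 0 against 0 in H39 (52.5). In H24 it was -0.13 against -0.01 (1.5), and in H15 it was -0.44 against -0.07 (percentile 0), below all shuffles. Shuffling removes every regional pattern, so regional shifts of any kind give values far from the shuffles. Such shifts, shared or opposite, were not limited to the low lines. Descent of the low lines therefore stays an open hypothesis. DNA copy number was not measured here, and the test cannot separate it from other regional regulation.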
